A study of Danio rerio with 6 samples.

How the data were processed

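RNA came from whole untreated larvae at 5 days post fertilization, 30 larvae per sample, kept in a light-dark cycle; per the labels' protocols, polyadenylated RNA was selected and stranded libraries were sequenced as paired reads of 75 bases. There were 6 samples, 3 per labelled genotype, with replicate numbers 1 to 3 in each group. Groups and replicate numbers were taken from the labels, and each table's sample from the submission's own record of its files. The names of the deposited tables run against the genotype labels and were not used to group samples.

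Each sample had a gene abundance table of coverage, FPKM and TPM values which, per the file headers, has the layout that StringTie writes. The submitters' processing notes name STAR 2.5.3a, StringTie 1.3.3b and DESeq2 1.16.1 and the builds danRer11 and hg38, without the role of each. Coordinates are printed as the deposited tables give them; that danRer11 is their build is not given in the sources used here beyond those notes. The deposited coverage is a mean signal per base, the deposited FPKM is scaled for length and depth, and the deposited TPM sums to 1000000 in each table. A table of the whole series holds the authors' own test per gene, whose columns are those of DESeq2 per the file headers: a mean signal of normalized counts, a log2 fold change with its standard error, a Wald score and 2 columns of p-values. In the row with the smallest p, the authors' adjusted p is 94973 times the p. If the adjustment was that of Benjamini and Hochberg, it covered at least as many tests, more than the 32519 genes listed in the deposited table. How the authors treated reads that match several near-identical genes is not given in the sources used here, so values of tandem copies such as crystallins, elastases and the globins are uncertain.

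The tables list 32520 genes. Rows of 1 gene were summed where a table held several. Names were taken from a table of Ensembl identifiers, which gave 29201 genes a symbol. For 10806 genes with an upper-case family symbol, the paralog was named where the RefSeq gene table of assembly GRCz12tu held exactly 1 matching symbol on the same chromosome. Another 1786 genes keep the family symbol, such as FOS, and 3319 have none. A list entry known only by a family symbol counted every gene with that symbol.

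The design set before the data were examined was a quasi-likelihood test on counts or, without counts, limma on TPM. The files used here hold no counts per sample, so the second was used: limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(TPM + 0.5), for the 20330 genes with at least 1 TPM in at least 3 samples, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. Fold changes from limma are on the log2(TPM + 0.5) scale, which understates the change of low genes, and are libraries labelled −/− minus libraries labelled +/+. Tested on simulated values for 20330 genes in this comparison, the fit recovered 72% of 100 genes changed by 1 and 94% of 100 genes changed by 2 on the log2 scale, with 8 false calls. The simulated noise was independent between genes and few genes were changed, unlike in these data. Recovery and false calls in the real comparison may therefore differ. Absolute depth is not known from TPM; the most common ratio of coverage to FPKM gave relative depth.

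The 35 gene lists, with 1281 entries of which 1135 matched a gene, were written before the data were examined. Each list was tested against other genes with camera at a preset correlation of 0.01, repeated with the estimated correlation, and tested with fry. Because the median log2 fold change of all genes was 0.22, camera can place a list below other genes when its own median is near 0. Genes to name were fixed by a rule set before the data were examined: all STIM and ORAI genes; the 8 largest changes each way among called genes with an informative symbol, at least 1 TPM in a group mean and groups that do not overlap; and the 4 members with the smallest p of each list that passed camera or held at least 3 called members. This gave 146 genes, of which the text prints a part. Analyses outside R used Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1.

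Whether equal replicate numbers pair the samples was checked by correlating deviations from the group means across genes. Replicates 1, 2 and 3 correlated with their counterparts at 0.25, 0.19 and 0.48. The numbers passed a rule for pairing that asks for every such correlation to exceed 0.1. This rule cannot establish pairing, since the deviations within a group cancel out for each gene. If replicate 3 departs alike in both groups, replicates 1 and 2 correlate across the groups as well. The calls and list tests reported come from the fit without the block, as set before the data were examined, and values with the block are given where they change a call. The pairing comes from the data, since no label names a shared clutch or day, and replicate 1 labelled +/+ correlated more with replicate 2 labelled −/− (0.29). The numbers in the names of the deposited tables differ from the replicate numbers of the labels, would pair the samples in another way and were not used. Correlations between replicates of 1 group were 0.982 to 0.995 on log2 values, and no tables held identical values. The alternatives were quantile scaling, no filter, a mean of at least 5 TPM, pseudocounts of 0.1 and 1, FPKM in place of TPM, the replicate block, leaving out each library, a fold threshold, and other set tests. Rescaling TPM by the median gene ratio (over genes of at least 1 TPM in all 6 libraries), the same with the block, and TPM recomputed without mitochondrial genes were added after seeing the data, as was a comparison of each list's median with 10000 random lists matched on gene span and mean TPM.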

Results

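Polyadenylated RNA was sequenced from whole zebrafish larvae at 5 days post fertilization, with 30 larvae pooled into each RNA sample. The labels put 3 samples in a group homozygous for mutations in both stim2a and stim2b and 3 samples in a group that is wild type at both genes. These genes encode STIM2 proteins, sensors of calcium in the endoplasmic reticulum that open ORAI channels in the plasma membrane. The groups are called libraries labelled −/− and libraries labelled +/+ throughout, because the RNA of the targeted genes goes against the labels. The deposited values are TPM, the share of transcripts scaled to the same total in every library, which keep no depth. The ratio of coverage to FPKM, proportional to the bases aligned, lay between 4.64 and 5.93 over the 6 libraries. Between 19582 and 20363 genes reached 1 TPM per library. The 200 most abundant genes held 56.1% to 59.6% of TPM in the libraries labelled +/+ and 52.9% to 56.8% in those labelled −/−. Transcripts of the mitochondrial chromosome made up 10.27%, 9.68% and 8.50% of TPM in the libraries labelled +/+ and 7.17%, 9.29% and 6.93% in those labelled −/−. The labels do not say that the pools came from separate clutches, so p-values measure only the spread between these samples.

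The first comparison asked whether the targeted genes differ between the labelled genotypes. Both were lower in the libraries labelled +/+. The gene stim2a (ENSDARG00000074867.4, chromosome 1, 14466860 to 14488074) stood at 0.328 ± 0.075 TPM (SD, n = 3) in the libraries labelled +/+ and at 1.31 ± 0.10 TPM (SD, n = 3) in those labelled −/−, a ratio of means of 3.98. The gene stim2b (ENSDARG00000001776.8, chromosome 7, 62320134 to 62439872), which the name table lists under the family symbol STIM2, stood at 0.580 ± 0.128 TPM and 1.57 ± 0.258 TPM (SD, n = 3 each), a ratio of 2.71. The lowest stim2a value among the libraries labelled −/− was 1.199 TPM and the highest among those labelled +/+ was 0.403 TPM, and for stim2b these values were 1.35 and 0.722 TPM. The limma log2 fold change on the log2(TPM + 0.5) scale was 1.13 ± 0.13 (SE) for stim2a, adjusted p = 0.00213, and 0.94 ± 0.15 (SE) for stim2b, adjusted p = 0.00871. Without replicate 2 labelled +/+, stim2b missed the threshold with a log2 fold change of 0.87 and adjusted p = 0.0546. The exact two-sided permutation test gave p = 0.1 for each gene, the smallest that 3 samples against 3 can give. In the authors' deposited table, the log2 fold change was −1.73 ± 0.177 (SE) for stim2a and −1.19 ± 0.18 (SE) for stim2b. That table does not state its direction, and both genes lie close to the lower limit of the expression filter.

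The related genes of the same calcium entry pathway gave no call in the fit of all 6 libraries without the replicate block, with TPM as deposited. The sensor stim1a stood at 10.5 ± 2.36 TPM in the libraries labelled +/+ and 14.6 ± 3.01 TPM in those labelled −/− (SD, n = 3 each), adjusted p = 0.0925 by limma, and stim1b at 3.51 ± 0.523 and 3.83 ± 0.628 TPM, adjusted p = 0.595. The channel gene orai1a stood at 8.27 ± 0.344 and 6.71 ± 0.467 TPM, adjusted p = 0.0684; its log2 fold change of −0.28 became −0.50 after rescaling by the median gene ratio, where it was called lower (adjusted p = 0.0155), as it was with quantile scaling (0.015) and with FPKM (0.0297). For orai1b the means were 2.12 and 2.75 TPM, adjusted p = 0.0898, and for orai2 they were 4.37 and 5.72 TPM, adjusted p = 0.149. With the replicate number as a block, orai1a passed as lower in the libraries labelled −/− (adjusted p = 0.0236), and stim1a (0.0341), orai1b (0.0308) and orai2 (0.0300) passed as higher. With the block and the rescaling together orai1a kept its call (0.00248), while stim1a, orai1b and orai2 did not pass (0.188, 0.281 and 0.358), their log2 fold changes being 0.23, 0.12 and 0.12 after rescaling against 0.45, 0.31 and 0.33 before. Without the block, stim1a passed when replicate 3 labelled +/+ (0.0275) or replicate 2 labelled −/− (0.0373) was left out. The log2 fold change of stim1b was 0.11 with TPM as deposited and −0.10 after rescaling by the median gene ratio. Of the 7 members, 2 were called over all genes, and the same count passed when adjusted over the list alone; after rescaling 2 were higher and 1 lower.

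**Figure D1:**
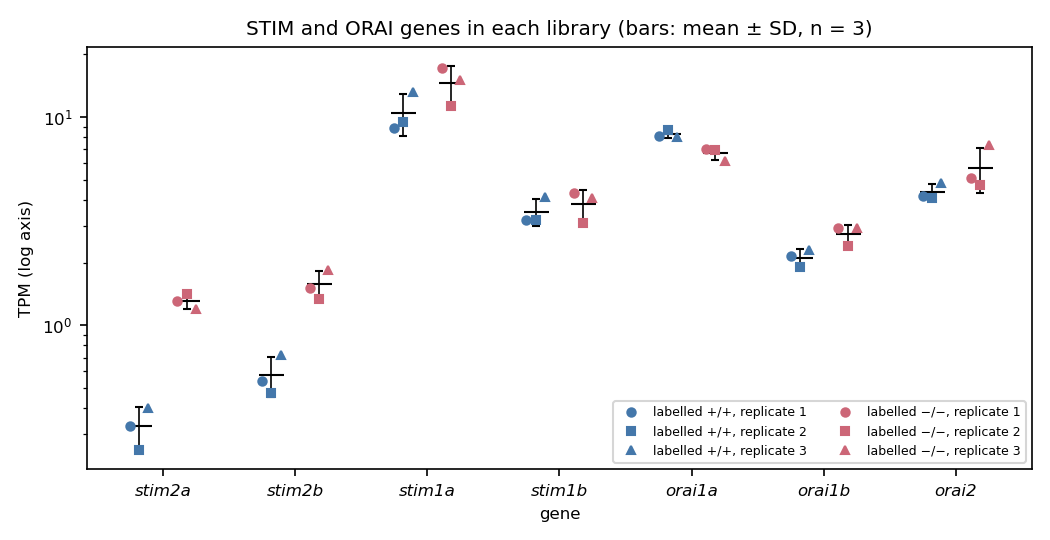
TPM of the STIM and ORAI genes on a log axis, with 1 point per library, blue for libraries labelled +/+ and red for libraries labelled −/−, and black bars for the mean ± SD (n = 3). For stim2a and stim2b all 3 libraries labelled +/+ lie below all 3 labelled −/−, at means of 0.328 against 1.31 TPM and 0.580 against 1.57 TPM.

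The second comparison asked which genes differ across the transcriptome. Directions follow the labels, which stim2a and stim2b go against. Among genes with an informative symbol, the largest increases in the libraries labelled −/− included the neuronal activity gene npas4a, the gene named FOS (an immediate-early transcription factor), the lens crystallins crybb1 and crybb1l1, and nxph1, a secreted neurexin ligand. Among such genes the largest decreases included anxa3a, an annexin, and cdc26, a subunit of the anaphase-promoting complex, both listed at 0 in every library labelled −/−. limma called 8046 of 20330 tested genes at an adjusted p under 0.05, of which 6265 were higher and 1781 lower in the libraries labelled −/−. The median log2 fold change of all tested genes was 0.22 with TPM as deposited and 0.01 after rescaling by the median gene ratio, and this rescaling gave 4612 higher and 4433 lower calls. A log2 fold change of at least 1 in size was reached by 1150 called genes, 961 higher and 189 lower. There were 736 such genes (432 and 304) after rescaling by the median gene ratio and 702 (384 and 318) with quantile scaling. Without each library in turn there were 292 to 1675. With the replicate block 11960 genes were called, 9265 higher and 2695 lower. The groups did not overlap for 55.8% of tested genes, where chance gives 10% for 3 against 3.

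Replicate 3 lay apart from the rest of its group under both labels. On the first principal component, which held 79.6% of the variance, replicate 3 labelled +/+ scored −18.1, against −52.0 and −46.4 for replicates 1 and 2 of that label. Replicate 3 labelled −/− scored 63.4, against 29.9 and 23.2 for replicates 1 and 2 of that label. Its correlations with these 2 were 0.983 and 0.982, and those of replicate 3 labelled +/+ with its own group 0.989 and 0.991. Without replicate 3 labelled +/+, 9525 genes were called, 8016 higher and 1509 lower in the libraries labelled −/−. Without replicate 1 labelled +/+ the calls fell to 606 (396 higher and 210 lower), and without replicate 2 labelled +/+ to 430 (266 and 164). Leaving out replicate 1 labelled −/− gave 4062 calls (2887 and 1175), and leaving out replicate 3 labelled −/− gave 4155 (3027 and 1128).

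The 8 largest changes in each direction were taken among called genes with an informative symbol, at least 1 TPM in a group mean and groups that did not overlap. This rule left out ENSDARG00000111123.1, a gene without a symbol. It was listed at 0 TPM in each library labelled +/+ and at 1072, 763.8 and 606.2 TPM in those labelled −/−. Among the increases, npas4a rose from 0.316 ± 0.053 to 3.57 ± 1.22 TPM (SD, n = 3 each), a log2 fold change of 2.28 ± 0.21 (SE, adjusted p = 0.000873). FOS stood at 0.808, 1.09 and 1.34 TPM in the libraries labelled +/+ and at 57.2, 8.24 and 6.495 TPM in those labelled −/− (log2 fold change 3.28 ± 0.70, SE, adjusted p = 0.0161), so that its mean rested largely on replicate 1. The intermediate filament gene vimr1 rose 5.40-fold, from 4.43 ± 1.27 to 23.9 ± 6.37 TPM, and scpp9, a secretory calcium-binding phosphoprotein, from 0.136 ± 0.031 to 5.31 ± 2.71 TPM. The means of crybb1 were 19.1 ± 5.15 and 118.2 ± 65.9 TPM, those of crybb1l1 9.26 ± 4.47 and 50.2 ± 24.9 TPM, and those of nxph1 5.74 ± 3.64 and 26.1 ± 6.00 TPM. Under this rule the increase with the largest log2 fold change (4.36) was that of tfpt, a chromatin remodelling subunit. It was listed at 0, 0.854 and 0 TPM in the libraries labelled +/+ and at 14.1, 14.3 and 12.9 TPM in those labelled −/−. The authors' deposited table gave tfpt a log2 fold change of −0.321 ± 0.25 (SE), much smaller in size than 4.36, with an adjusted p of 0.504. Without replicate 1 or without replicate 2 labelled +/+, FOS, crybb1 and crybb1l1 missed the threshold (highest adjusted p 0.0686, 0.0553 and 0.063), and nxph1 did so without replicate 2 (0.0558).

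The same rule left out ENSDARG00000105829.2, a gene without a symbol, from the decreases. It was listed at 40.36, 45.66 and 40.63 TPM in the libraries labelled +/+ and at 0.02187, 0.03669 and 0 TPM in those labelled −/−. Among the 8 largest decreases under this rule were 4 genes listed at 0 in all 3 libraries labelled −/−. In the libraries labelled +/+, anxa3a stood at 21.3, 22.1 and 24.3 TPM, cdc26 at 16.6, 16.6 and 22.1 TPM, the elastase gene cela1.5 at 8.97, 11.6 and 10.31 TPM, and the fibroblast growth factor receptor gene fgfr1bl at 3.90, 2.96 and 3.58 TPM. Their adjusted p lay between 2.08e-07 and 1.96e-05 by limma. The Hsp90 cochaperone gene ahsa1a stood at 7.47 ± 2.97 TPM in the libraries labelled +/+ and at 0.0876 ± 0.056 TPM in those labelled −/− (SD, n = 3 each). The selenoprotein gene selenol was listed at 6.23, 7.59 and 7.32 TPM against 0.243, 0 and 0.132 TPM, and ecm1a, which encodes an extracellular matrix protein, at 5.88, 4.57 and 3.43 TPM against 0.111, 0 and 0.114 TPM. The remaining gene of the 8, cnpy4, was listed at 10.8, 11.4 and 8.69 TPM against 0, 2.53 and 0 TPM, lost its call without replicate 1 or 2 labelled +/+ (highest adjusted p 0.0576), and had a log2 fold change of 0.22 with no adjusted p in the authors' deposited table. Because 0 was listed for cdc26, a gene that dividing cells need, a listed 0 is not read as absence of the RNA.

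Genes of neurons, rod photoreceptors and the immediate-early response were higher in the libraries labelled −/−. Of 40 tested neuronal genes 30 rose and none fell (33 rose adjusted over the list alone), and the median log2 fold change of the list lay 0.71 above that of all genes (camera adjusted p = 5.7e-05; adjusted p = 0.897 with an estimated correlation). The synaptic vesicle fusion gene snap25b stood at 57.5 ± 16.3 and 132.4 ± 27.0 TPM (SD, n = 3 each), the synaptic vesicle gene sypa at 42.8 ± 5.57 and 80.1 ± 17.5 TPM, and the synaptic adhesion gene nlgn1 at 1.11 ± 0.179 and 3.07 ± 0.933 TPM. Genes of GABA and glutamate signalling included 35 that rose and 1 that fell of 53 (40 and 1 adjusted over the list alone), with a median 0.60 above all genes (camera adjusted p = 5.7e-05; adjusted p = 0.897 with an estimated correlation). Its members gabrd, a GABA receptor subunit, and slc6a1a, a GABA transporter, rose 2.51-fold and 2.76-fold. These 5 genes lost their calls without replicate 2 labelled +/+, and all of them except snap25b also without replicate 1, with a highest adjusted p of 0.0623 for sypa. The level of the neuronal list also differed within the groups: after centring each gene and library, its median was −0.48, −0.42 and −0.12 in replicates 1, 2 and 3 labelled +/+ and 0.19, 0.19 and 0.63 in those labelled −/−.

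Of 37 immediate-early genes, which respond to stimulation without new protein synthesis, 27 rose and none fell (30 rose adjusted over the list alone), with a median 0.84 above all genes (camera adjusted p = 1.42e-05; adjusted p = 0.897 with an estimated correlation). With each library left out in turn, that median lay 0.477 to 0.898 above all genes. The transcription factor gene klf2a rose 4.11-fold, from 13.7 ± 2.53 to 56.5 ± 2.74 TPM (SD, n = 3 each, adjusted p = 0.000148 by limma). The genes nr4a1 and egr1 rose 2.59-fold and 4.66-fold. Their calls and that of klf2a held without each library in turn.

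Of 25 rod genes 21 rose and none fell (23 rose adjusted over the list alone), with a median 0.69 above all genes (camera adjusted p = 1.42e-05; adjusted p = 0.897 with an estimated correlation). The cyclic nucleotide-gated channel gene cngb1b rose 2.81-fold, from 1.61 ± 0.191 to 4.52 ± 1.07 TPM, and the arrestin gene sagb from 169.1 ± 19.2 to 284.0 ± 34.0 TPM (SD, n = 3 each). The call of sagb was lost without replicate 2 labelled +/+ (adjusted p = 0.0541). Of 37 cone genes 20 rose and 1 fell (21 and 1 adjusted over the list alone), with a median 0.19 above all genes (camera adjusted p = 0.0187; adjusted p = 0.897 with an estimated correlation). With each library left out in turn, the cone median lay 0.112 to 0.25 above all genes. The set call for cones by camera was lost after rescaling by the median gene ratio (adjusted p = 0.0859) and with the replicate block (0.0739). The cone phosphodiesterase genes pde6ha and pde6c rose 2.66-fold and 2.91-fold, pde6ha from 101.0 ± 7.20 to 268.7 ± 38.8 TPM. Of 26 genes of other retinal cells 12 rose and 1 fell (14 and 1 adjusted over the list alone), among them the retinal homeobox genes rx1 (3.64-fold) and rx2 (2.69-fold). That list had a camera adjusted p of 0.0397, an adjusted p of 0.897 with an estimated correlation, and lost its call without replicate 3 labelled +/+ (0.0639), replicate 2 labelled −/− (0.114) or replicate 3 labelled −/− (0.108), and with a mean of at least 5 TPM (0.264).

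After rescaling by the median gene ratio 29 neuronal genes rose and 3 fell, and the counts were 32 and 2 for GABA and glutamate signalling, 26 and 0 for immediate-early, 18 and 0 for rod, 14 and 3 for cone and 11 and 3 for other retinal genes. Tested with fry in 1 direction on TPM as deposited, only the immediate-early list of these passed (adjusted p = 0.0452). The others had 0.0505 (rod and cone), 0.0717 (neuronal), 0.0748 (other retinal) and 0.0783 (GABA and glutamate). With TPM rescaled by the median gene ratio, the immediate-early (0.0185), rod (0.0185), cone (0.015) and neuronal lists (0.0487) passed fry in 1 direction. The other retinal (0.0602) and GABA and glutamate lists (0.0642) did not. The difference of replicate 3 from replicates 1 and 2, relative to all genes, was 0.13 among the libraries labelled +/+ and 0.44 among those labelled −/− for GABA and glutamate signalling, 0.09 and 0.26 for rod, −0.04 and 0.12 for cone and 0.11 and 0.21 for other retinal genes.

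**Figure D2:**
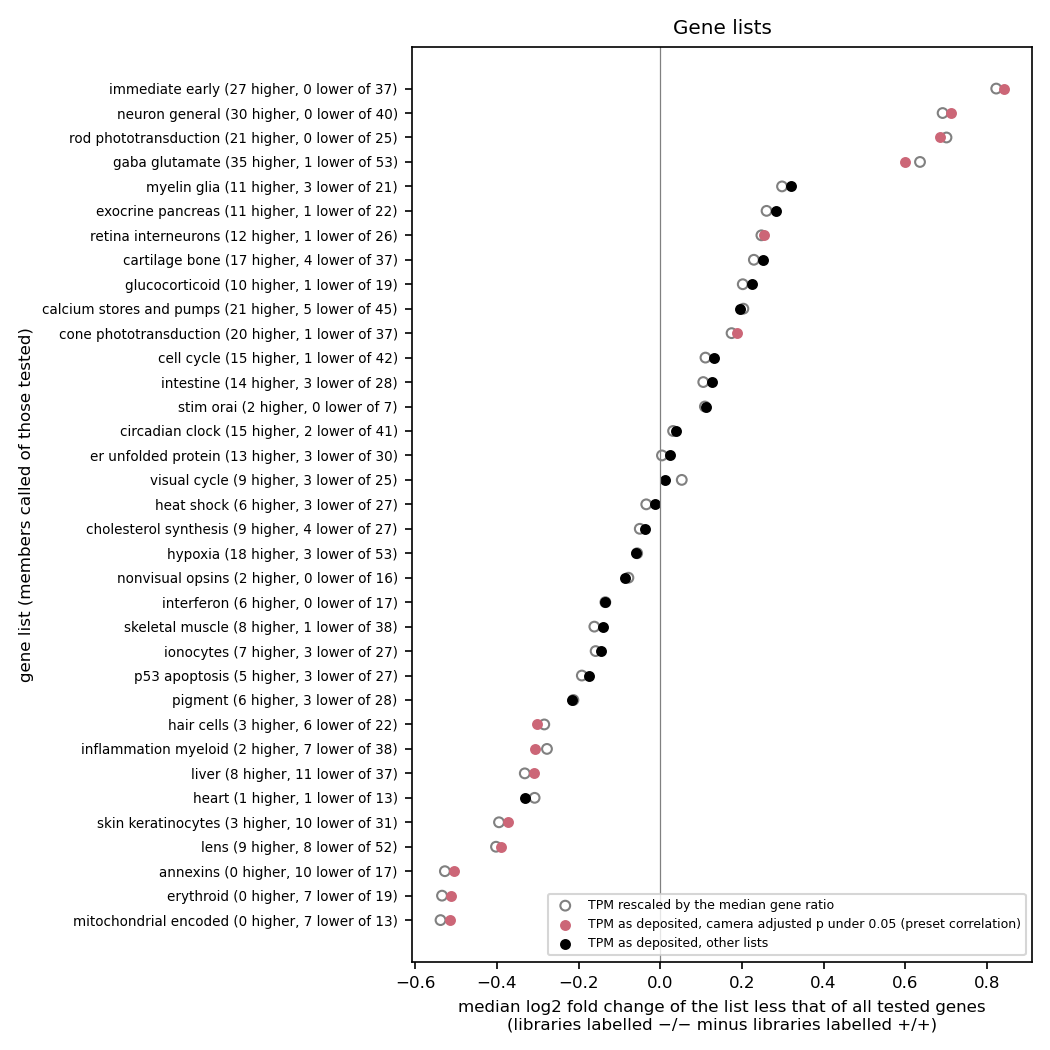
Median log2 fold change of each of 35 gene lists less the median of all tested genes, libraries labelled −/− minus libraries labelled +/+, with TPM as deposited (filled) and after rescaling by the median gene ratio (open); red marks a camera adjusted p under 0.05 with the preset correlation. Immediate-early, neuronal and rod lists lie 0.69 to 0.84 above all genes, and annexins, erythroid and mitochondrial genes lie 0.51 below or slightly further.

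Annexins, erythroid genes, mitochondrially encoded genes and skin keratinocyte genes were lower in the libraries labelled −/−. Of 17 annexins, proteins that bind membranes in a calcium-dependent way, 10 fell and none rose (10 fell and 2 rose adjusted over the list alone), with a median that lay 0.51 below that of all genes (camera adjusted p = 2.67e-06; adjusted p = 0.391 with an estimated correlation). The set tests included anxa3a, listed at 0 in every library labelled −/−, and none was run without it. The mean log2 fold change of the list was −0.58 and its median −0.28. Besides anxa3a, anxa5a stood at 28.3 ± 1.47 and 16.1 ± 0.624 TPM (SD, n = 3 each). The means of anxa1c, which is also on the keratinocyte list, were 131.4 ± 9.61 and 73.8 ± 12.8 TPM (SD, n = 3 each). The call of anxa1c was lost without replicate 2 labelled +/+ (adjusted p = 0.0518). Of 19 erythroid genes 7 fell and none rose, also adjusted over the list alone (camera adjusted p = 3.21e-05; adjusted p = 0.873 with an estimated correlation). The red cell carbonic anhydrase gene cahz stood at 87.5 ± 2.39 and 46.8 ± 1.88 TPM, a fold of 1.87 towards the libraries labelled +/+ (adjusted p = 0.000532 by limma). Of 13 mitochondrially encoded genes 7 fell and none rose, also adjusted over the list alone (camera adjusted p = 1.42e-05; adjusted p = 0.897 with an estimated correlation). MT-ND1, a subunit of respiratory complex I, stood at 6045 ± 275.3 and 4534 ± 350.3 TPM, and its call was lost without replicate 1 or 2 labelled +/+ (highest adjusted p 0.0684). Of 31 keratinocyte genes 10 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 7.86e-05; adjusted p = 0.391 with an estimated correlation; camera adjusted p = 0.0676 with quantile scaling, which ends the call), with the keratin gene cyt1l at 3959 ± 436.5 and 2527 ± 85.1 TPM. By fry in 1 direction on TPM as deposited the annexins (adjusted p = 0.00118) and keratinocyte genes (0.0452) passed. The erythroid (0.0783) and mitochondrial genes (0.0697) did not. With TPM rescaled by the median gene ratio, the annexins (0.00507), keratinocyte (0.0258) and erythroid genes (0.00376) passed fry, and the mitochondrial genes (0.0597) did not. After rescaling by the median gene ratio the falls numbered 11 of the annexins, 13 of the erythroid, 8 of the mitochondrial and 18 of the keratinocyte genes. Against 10000 lists matched on gene span and mean TPM, a comparison added after seeing the data, the annexin and erythroid medians lay at percentiles 0.01 and 0.02, while the keratinocyte median of −0.15 and the mitochondrial median of −0.29 lay inside the central 95% of matched lists (−0.18 to 0.14 and −0.35 to 0.20). Relative to all genes, 3 of the 4 lists were also lower in replicate 3 than in replicates 1 and 2 of both labels, with differences of −0.27 for the annexins among the libraries labelled +/+ and −0.25 among those labelled −/−, −0.21 and −0.20 for the mitochondrial genes and −0.13 and −0.15 for the keratinocyte genes; for the erythroid genes these values were 0.07 and 0.13.

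In 4 further lists members moved both ways while the set lay below other genes by camera. Of 38 myeloid and inflammation genes 7 fell and 2 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.00314), and of 37 liver genes 11 fell and 8 rose, also adjusted over the list alone (0.0037). Of 52 lens genes 8 fell and 9 rose (8 and 7 adjusted over the list alone; camera adjusted p = 0.00263), and of 22 hair cell genes 6 fell and 3 rose (6 and 4 adjusted over the list alone; 0.039). These 4 lists had an adjusted p of 0.897 with an estimated correlation. After rescaling by the median gene ratio most called members of these 4 lists were lower: 14 fell and 1 rose of the myeloid, 13 and 4 of the liver, 19 and 7 of the lens and 9 and 2 of the hair cell genes. The complement gene c3a.2 fell from 26.0 ± 1.86 to 13.3 ± 1.28 TPM, and the apolipoprotein gene apobb.2 from 1.67 ± 0.055 to 0.483 ± 0.037 TPM (SD, n = 3 each). The detoxification enzyme gene cyp3a65 rose 4.52-fold, from 50.8 ± 25.2 to 229.8 ± 73.7 TPM. The means of the lens, liver and hair cell lists were 0.06, 0.03 and 0.04 while their medians were −0.17, −0.09 and −0.08. The set calls of the lens (0.0851) and hair cell lists (0.14) were lost after rescaling by the median gene ratio, those of the liver (0.445), lens (0.181) and hair cell lists (0.0782) with quantile scaling, and the hair cell call also with the replicate block (0.0739), no filter (0.0863) or FPKM (0.0795). Single libraries decided set calls as well: without replicate 3 labelled +/+ the liver and hair cell lists had a camera adjusted p of 0.0557 each, without replicate 1 labelled −/− the lens list had 0.636 and the hair cell list 0.0754, and without replicate 3 labelled −/− the myeloid list had 0.0528. The liver median of −0.09 lay inside the central 95% of lists matched on gene span and mean TPM (−0.15 to 0.15). Replicate 3 also differed from replicates 1 and 2, relative to all genes. For the lens list this was −0.553 among the libraries labelled +/+ and 0.623 among those labelled −/−, each larger in size than the −0.389 between the groups. In the same order the values were −0.025, −0.29 and −0.306 for the myeloid list. They were 0.006, −0.319 and −0.309 for the liver and 0.018, 0.101 and −0.301 for the hair cell list.

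**Figure D3:**
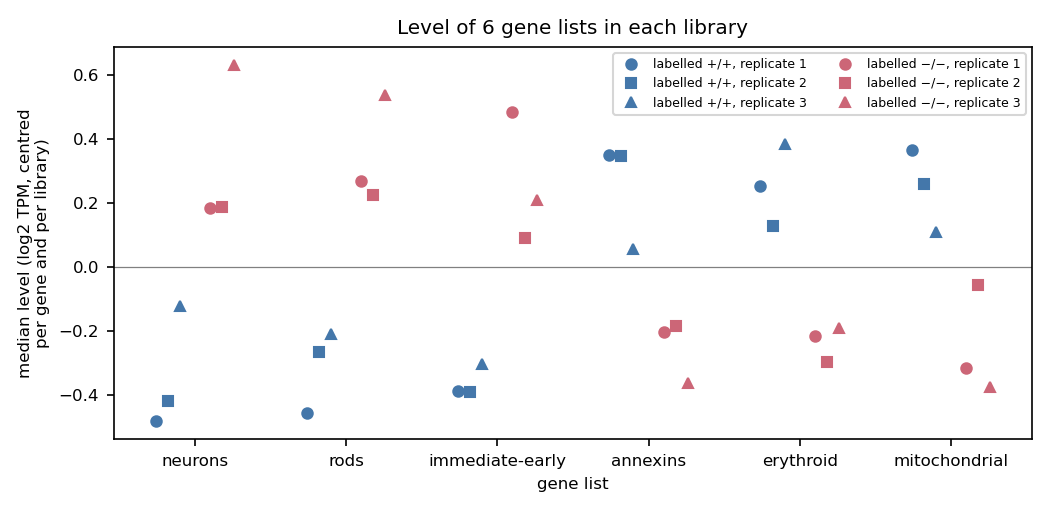
Median level of 6 gene lists in each library, in log2 TPM centred per gene and then per library, with blue points for libraries labelled +/+, red points for libraries labelled −/− and a marker shape for each replicate number. The neuronal list runs from −0.48 to −0.12 in the libraries labelled +/+ and from 0.19 to 0.63 in those labelled −/−, with replicate 3 highest in both.

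The authors' deposited table of differential expression allowed a gene by gene comparison with the calls above. In the authors' deposited table, 8737 genes had an adjusted p under 0.05, of which 3689 had positive and 5048 negative log2 fold changes, and 1424 also reached 1 in size. Of 20322 genes with an adjusted p in both, 6377 were called in both, where independent calls would share 3214. Both tests rest on the samples of this series, so an overlap above that number adds no separate evidence. All 6377 had the opposite sign to libraries labelled −/− minus libraries labelled +/+, and across the genes called here the log2 fold changes of the authors' deposited table and of limma correlated at Pearson r = −0.97 (across genes, which are not independent replicates). Of the genes called here by limma with a log2 fold change of at least 1 in size, 22 that were higher and 8 that were lower in the libraries labelled −/− had an adjusted p of 0.05 or more in the authors' deposited table.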

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

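TPM rescaled by the median gene ratio, alone or with the replicate block, and TPM without mitochondrial genes were alternatives chosen after seeing the data. No result changed direction past its threshold under any alternative run. Total calls were 8046, against 11960 with the replicate block, 11767 with the block and rescaling together, 5238 with a mean of at least 5 TPM, where fewer genes were tested, 1150 with a log2 fold change of at least 1 in size, and 430 to 9525 without each library in turn. Higher calls were 6265, against 4161 with quantile scaling, 3919 with a mean of at least 5 TPM, and 266 to 8016 without each library. Lower calls were 1781, against 4229 with quantile scaling, 4433 with rescaling by the median gene ratio, 2837 with FPKM, 2695 with the replicate block, 5800 with the block and rescaling together, and 164 to 1509 without each library. Both scalings set the median of all genes near 0 (−0.0066 and 0.0112 against 0.221), which moves calls from higher to lower; for the other changes the cause was not tested. With camera 14 of 35 lists passed, 12 to 15 without each library in turn, and 0 with the estimated correlation. With fry 7 lists were called in 1 direction and 35 in either. The 7 were the annexin, immediate-early, keratinocyte, STIM and ORAI, visual cycle, interferon and glucocorticoid lists. With TPM rescaled by the median gene ratio, the visual cycle (fry adjusted p = 0.0684) and interferon lists (0.874) lost this call, and the others kept it. With TPM as deposited, most lists that passed camera thus did not pass fry in 1 direction. Of the lists that had failed, fry called the rod, cone, neuronal, erythroid and hair cell lists (0.0185) after that rescaling. The other retinal, GABA and glutamate, mitochondrial, myeloid (0.0602), liver (0.183) and lens lists (0.488) still did not pass. Calls ended by quantile scaling, a filter or FPKM stand beside those lists in the report. Calls were gained by the pancreas (0.0124), calcium store (0.0325) and cartilage and bone lists (0.0203) with quantile scaling, the clock list with no filter (0.0268), and the skeletal muscle list with the block and rescaling together (0.0452). The log2 fold change of stim2b was 0.868 to 1.03 without each library labelled +/+, and stim2b missed the threshold in 1 of these 3 fits; with a library labelled −/− left out, stim2a and stim2b were not tested, since they then failed the expression filter. In the other settings stim2a (0.797 to 1.729) and stim2b (0.701 to 1.302) remained past the threshold, apart from the stricter filter, which removed both. The authors' deposited table had 8737 calls and 1424 with a log2 fold change of at least 1 in size. Of the 146 named genes, 74 lost the call without replicate 1 and 89 without replicate 2 labelled +/+, 8 after rescaling by the median gene ratio, and at most 4 under each other setting; the block ended no call among them and added 4. Beside the values printed in the report for the cone and hair cell lists and the 4 STIM and ORAI genes, the block changed no call of a named gene or list that is reported. DESeq2 size factors, the DESeq2 test, limma-voom and a surrogate variable were planned and not run, because the files used here hold no counts per sample. The depth behind each TPM is not known; in the authors' deposited table the mean normalized counts were 301.9 for stim2a and 226.1 for stim2b.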

Other observations

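The tests of the neuronal list and of the genes listed near 0 were chosen after the result was seen; for the neuronal list the correlations over all genes had been seen first. The tests of the genotype labels, of linkage and of other splits of the samples were set before the data were examined.

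Other fixed lists gave no set call by camera with TPM as deposited, all libraries and the filter of 1 TPM in 3 samples but held single genes with large changes; directions follow the labels, which stim2a and stim2b go against. Of 41 circadian clock genes 15 were higher and 2 lower in the libraries labelled −/− (16 and 2 adjusted over the list alone; camera adjusted p = 0.23, and 0.0268 with no filter): the repressor genes nr1d2a and bhlhe40 rose 2.07-fold and 2.12-fold and per3 2.19-fold. Of 53 hypoxia genes 18 were higher and 3 lower (18 and 4 adjusted over the list alone; camera adjusted p = 0.752), with arnt, a partner of hypoxia-inducible factors, at 2.08 ± 0.458 and 7.68 ± 1.81 TPM and ankrd37, a hypoxia-inducible gene, at 3.73 ± 0.146 and 1.02 ± 0.225 TPM (SD, n = 3 each). Of 19 glucocorticoid genes 10 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.18, fry adjusted p = 0.0452 in 1 direction). Among them pomca, the corticotropin precursor, rose 2.52-fold. Of 27 ionocyte and calcium hormone genes 7 were higher and 3 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.48), and cyp24a1, the enzyme that inactivates vitamin D, rose 4.02-fold, from 2.99 ± 0.690 to 12.02 ± 2.29 TPM. Of 45 genes of calcium stores and pumps 21 were higher and 5 lower (24 and 6 adjusted over the list alone; camera adjusted p = 0.23, and 0.0325 with quantile scaling); the plasma membrane calcium pump genes atp2b3a and atp2b3b rose 2.66-fold and 2.74-fold, and lost their calls without replicate 1 or 2 labelled +/+ (highest adjusted p 0.0672 and 0.061). After rescaling by the median gene ratio the balance turned for the ionocyte and calcium hormone genes (4 higher and 10 lower); it was 10 and 4 for the clock, 13 and 10 for the hypoxia, 7 and 3 for the glucocorticoid and 18 and 9 for the calcium store genes.

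Digestive and glial genes also held large single changes. Of 22 exocrine pancreas genes 11 were higher and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 0.109), and the carboxypeptidase gene named CPA1 rose from 355.5 ± 110.0 to 1275 ± 156.3 TPM (SD, n = 3 each), 3.59-fold, while cela1.5, an elastase gene, was listed at 0 in the libraries labelled −/−. The pancreas list was called by camera with quantile scaling (adjusted p = 0.0124) and without replicate 2 (0.0424) or 3 labelled +/+ (0.0424) or replicate 3 labelled −/− (0.00398). Of 28 intestinal genes 14 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.456), with the chitinase gene chia.3 2.92-fold higher. Of 21 myelin and glia genes 11 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.591), with the claudin gene cldnk 1.70-fold higher. Of 28 pigment genes 6 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.219), with gch2, needed for pteridine pigment, at 34.0 ± 4.80 and 12.4 ± 3.44 TPM. After rescaling by the median gene ratio the balance turned for the pigment genes (4 higher and 8 lower); it was 5 and 1 for the pancreas, 10 and 6 for the intestinal and 10 and 5 for the glial genes. The calls of CPA1, chia.3, cldnk and gch2 held without each library in turn.

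The RNA of the targeted genes runs against the genotype labels. Mislabelled genotype groups are a candidate explanation: that test needed both genes to be lower in all 3 libraries labelled +/+ than in every library labelled −/−, and 6 of the 6 values were. The names of the deposited tables run against the labels as well, and the authors' deposited table, which does not state its direction, has negative values for both genes. A mutant RNA that is more abundant than the wild-type RNA stays open and was not tested, since reads over the mutated positions were not analysed here. Until this is settled, no direction given here can be assigned to the loss of stim2a and stim2b.

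The second pattern is that neuronal genes were higher in the libraries labelled −/−. Gene span, introns included, and TPM scaling are argued against as its only cause. The list median of 0.93 was at percentile 100 among 10000 lists matched on gene span and mean TPM (matched lists 0.06 to 0.40). It stayed at 0.703 after rescaling by the median gene ratio. Rescaling moves the genes of a library by nearly the same amount. The value of 0.703 thus follows largely from the list lying 0.71 above all genes and adds little to it. Transcript length was not tested. The matched lists were drawn at random, while the neuronal genes had an estimated correlation of 0.71. That percentile therefore overstates how unusual the list is. A gradient between libraries that also runs inside the groups may contribute, since relative to all genes the list was higher in replicate 3 than in replicates 1 and 2 by 0.303 among the libraries labelled +/+ and by 0.43 among those labelled −/−, against 0.71 between the groups. Across genes, which are not independent replicates, these differences within the groups correlated with each other at a Spearman coefficient of 0.57 and with the change between the groups at 0.62 and 0.68, and gene span with the change between the groups at 0.35. The immediate-early list did not follow the gradient in both groups (0.14 and −0.14), and an effect of the genotype on either list stays open, as untested.

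The third pattern is that 33 genes had at least 1 TPM in all 3 libraries of 1 label and under 0.05 TPM in all 3 of the other. Of these 31 were near 0 in the libraries labelled −/−, among them anxa3a, cdc26, cela1.5 and fgfr1bl, and 2 in those labelled +/+. No other split of the samples gave more than 1 such gene, but each mixes libraries of both labels, so few were possible. All 33 were called in the authors' deposited table, but a call there does not mean a value near 0. The smallest log2 fold change in size there was 1.49, for the gene named SMC1A. Haplotypes linked to the mutated genes are argued against as the general cause, since 0 of the 26 that are placed on a chromosome lie within 10 Mb of stim2a or stim2b; for the other 7, on unplaced scaffolds, this stays open. Haplotype or copy number differences between fish stocks at other loci may account for them: 15 had another such gene within 1 Mb, where 10000 random draws of as many tested genes gave a median of 2 and at most 10. Of these, 6 lie on chromosome 22 between 6527414 and 7539414, a region named after its values were seen; reads shared between neighbouring copies and an effect of the genotype stay open.

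Calls near the mutated genes gave no common direction. Within 10 Mb of either gene 40.1% of tested genes were called, against 39.6% elsewhere, an odds ratio of 1.02 (Fisher's exact test, two-sided, p = 0.813, adjusted over 9 tests 0.915). Within 5 Mb of stim2a 66 of 122 tested genes were called (54.1%), an odds ratio of 1.81 with a 95% interval of 1.24 to 2.63 (Fisher's exact test, p = 0.00148, adjusted 0.0133), which with the authors' deposited table was 1.36 (adjusted p = 0.364). Within 5 Mb of stim2b 26 of 93 were called (28.0%), an odds ratio of 0.591 (Fisher's exact test, p = 0.0251, adjusted 0.0565). Among genes with a mean of at least 5 TPM, the odds ratio within 5 Mb was 1.74 for stim2a and 0.458 for stim2b, and within 10 Mb of stim2b it was 0.653, each with an adjusted p of 0.0462 (Fisher's exact test).

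The 6 samples form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 8046 calls, 1 of the 10 splits gave as many (the real one), and the highest of the other splits gave 2. Each other split mixes libraries of both labels, so a difference between the labels adds to its spread and leaves few calls. The low counts of the other splits were thus largely set by the design and do not measure chance. The 3 other splits that part all replicate pairs gave 0 calls by limma and at most 136 genes at an unadjusted p under 0.05. The split of replicates 1 and 2 labelled +/+ and replicate 2 labelled −/− against the rest gave 2882 genes at an unadjusted p under 0.05, where the real split gave 10612.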
